A study of Mus musculus with 2 samples.

How the data were processed

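Total RNA of the left cerebral cortex of 14-day-old female B6CASTF1/J mice was sequenced as long reads in 2 libraries, per the labels. The labels number them as biological replicates 1 and 2 of 1 group; the sample description of replicate 1 can be read as a pool of several females, and both carry the same donor entry at the level of the strain, so p-values weigh the difference between these libraries against counting error alone. RNA spike-ins of the ERCC and SIRV sets were added, per the labels. Sequencing instrument and the versions of the aligner and annotator are not given in the sources used here.

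The deposited tables hold raw read counts per transcript model, 1 table per library, and list only models with at least 1 read; they come with the models' exon coordinates on mm10, counted from 1. Per the file headers, reads were aligned to mm10 with the GENCODE M21 annotation, and the annotation source field of the authors' models names TALON. The authors assigned each model to a gene and to a class: annotated, incomplete splice match, annotated splice sites in another combination, at least 1 splice site outside the annotation, antisense, intergenic, or Genomic. Model names outside the annotation are given per library, so models were matched between libraries by chromosome, strand and intron positions, and a chain that the tables class or assign differently in each library enters as labelled. Such disagreement between incomplete and full labels affected 525 of 24738 unannotated chains seen in both libraries (2.12%), with 0.582% and 0.566% of mouse reads. Genes that overlap or share reads with a near-identical copy are uncertain, since the tables give each read to 1 gene.

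Replicate 1 held 1087280 reads, of which 14936 (1.37%) were on ERCC spike-ins, and replicate 2 held 762376, of which 8856 (1.16%) were. RPM are reads scaled to a library total of 1000000 mouse reads. Annotated genes took 92.3% and 89.7% of mouse reads. Models with a single read numbered 81537 and 71985. The 16 spike-in RNAs with 100 or more reads had a median log2 ratio, replicate 2 over replicate 1 and against mouse reads, of -0.26. SIRV models were not analysed here.

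Gene counts are the sums over a gene's models. Genes with 10 or more reads in total were compared by a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment; log2 ratios use a pseudocount of 0.5 reads. The common dispersion was estimated with edgeR on TMM-scaled counts (factors 1.00 and 0.997) with an intercept alone; a model test between conditions could not be made with 1 group. The 22 gene lists were fixed before the data were examined: excitatory neurons, inhibitory neurons, astrocytes, myelinating oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus and meninges, red blood cells, striatal, hippocampal, and thalamic and cerebellar neurons, presynaptic and postsynaptic proteins, immature neurons, cell cycle, immediate early genes, mitochondrially encoded genes, imprinted genes, an X-linked and a Y-linked check, and neuronal RNA-binding proteins. A list's median level was placed among 10000 random lists of detected genes, and its median log2 ratio among 10000 lists drawn from the 200 genes nearest in mean expression to each member. Percentiles describe these libraries and are no p-values.

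Splice chains were counted as found in both libraries at 2 or more reads in 1 and 1 or more in the other. Isoform shares use annotated and full unannotated chains of genes with 20 or more such reads in each library; isoform use was tested by chi-square with 10000 simulated tables over isoforms with 5 or more reads in total. Exon inclusion is the share of spanning reads that contain an annotated alternative exon, in 80 splice genes fixed before the data were examined, with 20 or more spanning reads in each library; the libraries were compared by Fisher's exact test with Benjamini-Hochberg adjustment. Intervals of shares are Wilson 95% intervals. Reads are not corrected for duplicates, so intervals cover counting error only.

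Named genes were chosen by a rule set before the data were examined. It takes the 10 most abundant genes without mitochondrial genes and spike-ins; up to 3 of the most abundant members of each list, with members at 0 for lists of other tissues or sex; the 5 largest log2 ratios in each direction among adjusted calls with 50 or more reads, and up to 4 called members of a list; up to 30 alternative exons by spanning reads with a mean of 5 to 95%; the 5 most abundant unannotated chains and 3 unannotated loci; the 5 longest annotated multi-exon transcripts with 5 or more reads in each library; 10 list or splice genes whose second isoform holds 20% or more in both libraries; and the 5 smallest p of the isoform test, with ties ordered by chi-square. Names outside it are said to be so, stand for a detection limit or, as with Dcx, Tspan31, Kcnn2, Ywhag and the Nrcam exon, are examples chosen after their values were seen. Some genes that the rule takes, and a test of exons that change as the brain matures, are not reported here; list medians and counts include all members.

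The alternatives tried were TMM and DESeq2 median-of-ratios scaling, no filter and 50 or more reads, leaving out Genomic reads or all but annotated transcripts, a pseudocount of 2 reads, leaving mitochondrial genes out of the total, other minimum counts of chains and isoforms, counting or leaving out incomplete splice matches, and each library alone. Reassigning models to the gene they overlap most, giving each chain 1 label in both libraries, and leaving out the ribosomal RNA locus were added after seeing the data.

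The gene test, the comparison of lists with matched random lists, the isoform test and the exon test were tried on simulated data. The data were drawn from the real means and library sizes without the spread between libraries, so the rates below cover counting error only. Those of the gene test need not hold for genes near the minimum of 10 reads. The tests of possible causes in the later sections were not simulated. Of 100 genes changed 2-fold the gene test found 76% and of 100 changed 4-fold 100%, and 3.83% of its 183 calls were unchanged genes. A simulated list of 14 genes moved 2-fold lay at percentile 100. The isoform test found 91.4% of 200 genes moved by 40 percentage points, with 3.72% of calls on unchanged genes. The exon test found 100% of 10 exons moved by 25 points and called 1 unchanged exon among 39 exons. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.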

Results

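Long-read RNA sequencing measured the transcripts of the left cerebral cortex of 14-day-old female mice of the strain B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ. The series holds 1 group of 2 libraries, replicate 1 and replicate 2, labelled as biological replicates and each made from 2 µg of RNA. No second tissue, sex, age or treatment stands beside them, so the data describe what this tissue expressed and how far the libraries differed. Replicate 1 held 1072344 mouse reads on 133494 transcript models and replicate 2 held 753520 reads on 116334 models. Reads fell on 16904 annotated genes in replicate 1 and 16364 in replicate 2, of which 9729 and 8785 had 10 or more reads. Abundance is given as RPM, reads scaled to a library total of 1000000 mouse reads. A single read was worth 0.933 RPM in replicate 1 and 1.33 in replicate 2, and a count of 0 allowed up to 2.80 and 3.98 RPM. Values are means ± SD with n = 2 libraries unless both are given, and all intervals and floors cover counting error only.

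Among the 10 most abundant genes of the cortex, Calm2, which encodes the calcium sensor calmodulin, reached 3725 ± 394 RPM. The tubulin genes Tuba1a and Tubb2a stood at 5282 ± 359 and 4923 ± 153 RPM. Apoe, the lipid carrier made mainly by astrocytes, reached 5232 ± 157 RPM. Cpe, a peptide-processing enzyme, stood at 4000.0 ± 135 RPM, the ubiquitin gene Ubb at 3984 ± 356, the calmodulin-binding neuronal gene Nrgn at 2970 ± 144 and Ndrg4 at 2609 ± 161. Mbp, which encodes myelin basic protein, stood at 2908 ± 1083 RPM, with the widest spread of the 10.

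Astrocyte markers were abundant. Their 16 genes had a median of 402 RPM (266 on annotated transcripts alone), at percentile 100 of 10000 random lists of detected genes, led by Apoe, Sparcl1 (1735 ± 98.5 RPM) and Aldoc (1306 ± 29.96). The 17 excitatory neuron genes had a median of 26.9 RPM (percentile 92.5), led by Nrgn, the vesicular glutamate transporter Slc17a7 (1179 ± 92.3) and Camk2a (93.7 ± 4.54); on annotated transcripts alone the median was 13.5 RPM (percentile 45.6). The 16 inhibitory neuron genes had a median of 30.7 RPM (percentile 94.6), with Cck at 503 ± 67.2, the GABA-synthesising enzyme Gad1 at 247 ± 37.4 and Lamp5 at 185 ± 22.6. The 14 genes of myelinating oligodendrocytes had a median of 79.8 RPM (percentile 99.9), led by Mbp and Cnp (784 ± 177). Oligodendrocyte precursor genes stood lower, with a median of 17.9 RPM (percentile 73.7) and Olig1 at 160 ± 20.1, Olig2 at 66.5 ± 11.0 and Gpr17 at 48.8 ± 0.432. Microglial genes had a median of 51.1 RPM (percentile 98.9), with P2ry12 at 112 ± 6.09 and Csf1r at 96.6 ± 6.04. Endothelial and mural genes had a median of 20.1 RPM (percentile 79.3), with the tight-junction gene Cldn5 at 355 ± 27.2, Itm2a at 169 ± 6.22 and Rgs5 at 128 ± 12.3.

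Synaptic and growth-related genes were abundant, while dividing cells left few transcripts. The 23 presynaptic genes had a median of 380 RPM (percentile 100), led by Syp (1814 ± 152), Rab3a (1308 ± 15.5) and Snap25 (1223 ± 121). The 22 postsynaptic genes had a median of 70.8 RPM (percentile 100), led by Camk2b (716 ± 24.7), Grin1 (461 ± 34.2) and Gria2 (292 ± 8.70). Genes of immature neurons had a median of 207 RPM (percentile 100), with Tuba1a, Marcksl1 (1635 ± 180) and Tubb3 (698 ± 5.74) at the top, whereas Dcx, a marker of migrating neurons, had 4 and 5 reads. Neuronal RNA-binding proteins had a median of 66.8 RPM (percentile 99.9), led by Celf4 (497 ± 14.3), Khdrbs3 (399 ± 58.8) and Rbfox3 (357 ± 52.8); on annotated transcripts alone their median was 20.7 RPM (percentile 68.8). Immediate early genes, which respond to neuronal activity, had a median of 28.3 RPM (percentile 90.9), with Junb at 146 ± 23.7, Egr1 at 76.7 ± 0.356 and Dusp1 at 62.8 ± 10.0. Cell cycle genes had a median of 2.92 RPM (percentile 8.53); Pcna stood at 53.7 ± 4.56, Mcm5 at 12.3 ± 2.38 and Mcm2 at 9.70 ± 3.17, and Mki67 had no read in either library.

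Imprinted genes, expressed from 1 parental copy in at least some tissues, had a median of 42.3 RPM (percentile 99.7), or 26.0 on annotated transcripts alone (percentile 83.7). Reads were not separated by parental copy here. Snrpn stood at 1913 ± 181 RPM, Gnas at 1561 ± 11.3 and Ndn at 500 ± 28.3, and H19, Peg10 and Zdbf2 had no read. The X-linked list had a median of 21.5 RPM (percentile 71.0); Eif2s3x reached 84.0 ± 11.8 RPM and Ddx3x 31.4 ± 3.09, and Xist, the RNA of the inactive X chromosome, had 18 and 23 reads. None of the 7 Y-linked genes (Ddx3y, Uty, Kdm5d, Eif2s3y, Usp9y, Zfy1 and Sry) had a read. Mitochondrially encoded genes had a median of 21.9 RPM (percentile 82.7) and took 0.0467% and 0.0403% of mouse reads, with mt-Co1 at 171 ± 25.9 RPM, mt-Cytb at 54.1 ± 1.37 and mt-Nd2 at 31.3 ± 0.761; mt-Nd4l had no read.

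Genes of neighbouring regions and of blood were also present. Red blood cell genes had a median of 68.5 RPM (percentile 96.2), with Hba-a1 at 269 ± 46.2, Hbb-bs at 140 ± 21.4 and Hba-a2 at 68.5 ± 13.8, and Slc4a1 at 0. Striatal genes had a median of 18.5 RPM (percentile 72.5), with Ppp1r1b at 231 ± 71.5 and Penk at 69.9 ± 23.8. The hippocampal list had a median of 11.7 RPM (percentile 47.5), with Wfs1 at 156 ± 34.6, Fibcd1 at 21.9 ± 4.67, C1ql2 at 14.3 ± 0.431 and Dsp at 0. The thalamic and cerebellar list had a median of 11.5 RPM (percentile 48.9), with Rora at 49.5 ± 2.48, Car8 at 14.2 ± 4.29, Prkcd at 13.8 ± 1.09 and the cerebellar genes Pcp2 and Cbln3 at 0. The choroid plexus and meninges list had a median of 8.61 RPM (percentile 37.8), with Ttr at 25.2 RPM in replicate 1 and 256 in replicate 2, Dcn at 44.1 ± 20.2, Col1a1 at 32.5 ± 2.81 and Kl at 0.

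The levels of lists depended on the reads counted. On annotated transcripts alone, scaled to their own smaller total, the median was 20.6 RPM for choroid plexus and meninges (percentile 61.4), 10.8 for the X-linked list (percentile 33.8), 383 for immature neurons, 104 for red blood cells, 44.1 for immediate early genes and 33.5 for mitochondrially encoded genes. Without Genomic reads it was 6.29 for the hippocampal list (percentile 23.4) and 42.2 for RNA-binding proteins. Over the genes detected in 1 library, the median of cell cycle genes was 4.66 in replicate 1 and that of immediate early genes 45.1 in replicate 2.

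**Figure D1:**
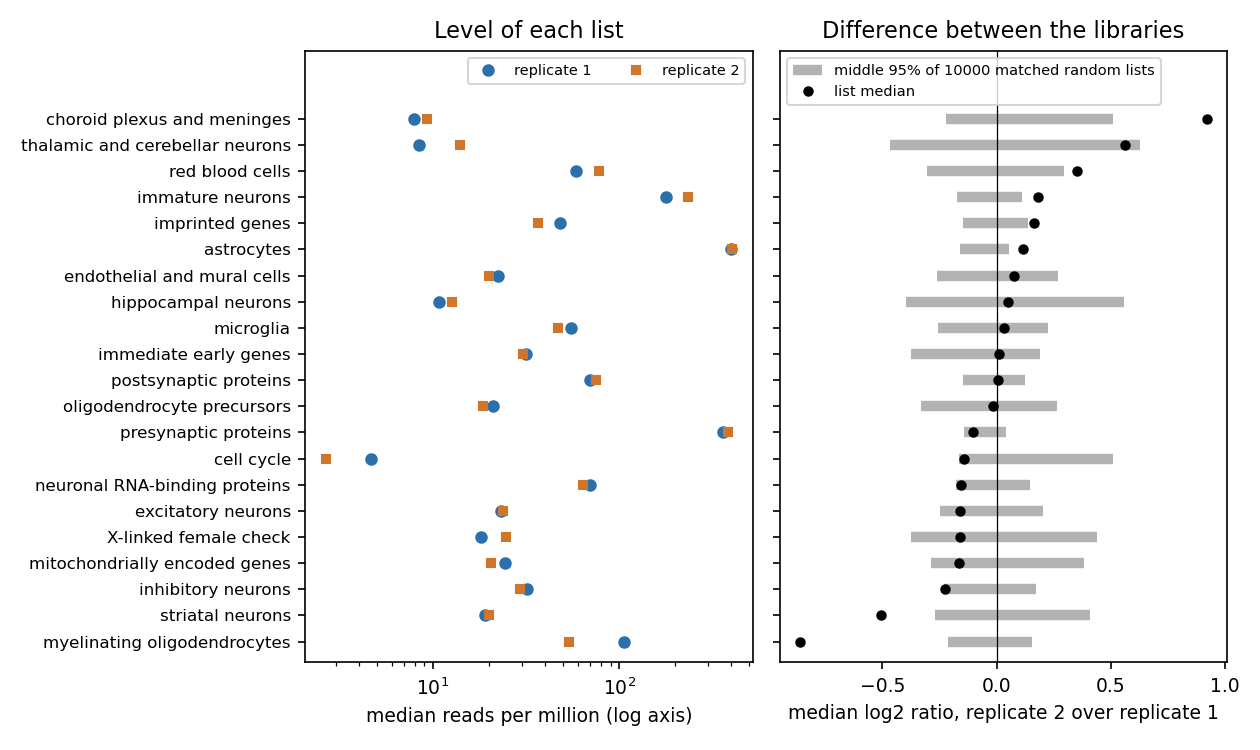
Median RPM of each gene list in replicate 1 (circles) and replicate 2 (squares) on a log axis, left, and the median log2 ratio of replicate 2 over replicate 1 for each list (points) against the middle 95% of 10000 random lists of matched expression (bars), right. The myelin list lies at -0.86 and the choroid plexus and meninges list at 0.92; the Y-linked list had no reads and is not drawn.

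The clearest difference between the libraries was in myelin. In replicate 2, 13 of the 14 genes of myelinating oligodendrocytes had a negative log2 ratio, with a median log2 ratio of -0.86, below all 10000 random lists of matched expression (percentile 0). Of these, 7 were lower in the test over all genes and 8 when adjusted over the list alone. Mbp fell from 3673 to 2142 RPM (log2 ratio -0.78; exact binomial test, adjusted p = 3.04e-75), Trf from 297 to 147 (log2 ratio -1.01) and Cnp from 909 to 660 (log2 ratio -0.46). The precursor list did not move with them, at a median log2 ratio of -0.01 (percentile 57.6) and with 0 genes called.

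In the other direction stood genes of immature neurons, with a median log2 ratio of 0.18 (percentile 99.7), or 0.07 without Genomic reads (percentile 97.9). Tuba1a (log2 ratio 0.14), Marcksl1 (0.23), Nnat (0.97) and Dpysl3 (1.02) were higher in replicate 2 in the exact binomial test over all genes. Adjusted over the list alone, 5 were. The test weighs counting error and not the spread between libraries, so a ratio as small as that of Marcksl1 shows a difference between these libraries alone. The Tuba1a call depended on how reads were given to genes, since the overlapping Gm49450 took 322 reads in replicate 1 and 1 in replicate 2. With overlapping same-strand models counted together, that locus had 5714 and 4171 reads (log2 ratio 0.055). The choroid plexus and meninges list had a median log2 ratio of 0.92 (percentile 99.8). Ttr, which encodes the thyroid hormone carrier transthyretin of choroid plexus, had 27 reads in replicate 1 and 193 in replicate 2 (log2 ratio 3.32; exact binomial test, adjusted p = 4.10e-43); 1 gene of the list was called over all genes and 2 adjusted over the list alone. Imprinted genes had a median log2 ratio of 0.16 (percentile 98.8), although the list's median level was 48.0 RPM in replicate 1 and 36.5 in replicate 2. The non-coding RNA Meg3 rose (log2 ratio 0.82), as did Nnat and Snhg11 (0.96), though without Genomic reads Nnat (-0.08) and Snhg11 (-0.75) turned negative, and Snrpn fell by 0.19 on the log2 scale; 4 were called over all genes and 6 adjusted over the list alone. On annotated transcripts alone Meg3 (log2 ratio 0.13), Snhg11 (0.42), Snrpn (-0.15), Tuba1a (0.11), Dpysl3 (1.45) and Calb2 (0.96) kept their direction and did not pass, and Tuba1a and Dpysl3 did not pass once models were reassigned to the gene they overlap most. Without Genomic reads the imprinted list lay at percentile 91.4. Of the striatal list, with a median of -0.51 (percentile 0.22), 1 gene was called and 2 adjusted over the list alone; Ppp1r1b, the dopamine signalling protein of striatal neurons, fell from 282 to 180 RPM. Astrocyte genes had a median of 0.12 (percentile 99.8) with 0 called over all genes and 0 adjusted over the list alone, and red blood cell genes 0.35 (percentile 98.8) with 0 and 1.

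The other lists lay within the middle 95% of matched random lists in the main setting. Without Genomic reads the excitatory (percentile 0.49), inhibitory (2.40) and postsynaptic (0.94) lists lay below it, as did cell cycle genes with a pseudocount of 2 reads (2.40) or after reassignment (2.21) and the inhibitory list after reassignment (2.27). Leaving out that class can take reads from 1 library alone. Camk2a of the excitatory list had Genomic reads for 0 of 97 reads in replicate 1 and 65 of 73 in replicate 2. How far such genes set the low lists without Genomic reads was not tested, so these lists allow no conclusion on expression in replicate 2. Among neuronal lists the median log2 ratio was -0.16 for excitatory neurons (percentile 11.8), -0.22 for inhibitory neurons (percentile 3.17), -0.10 for presynaptic genes (percentile 15.5), 0.01 for postsynaptic genes (percentile 65.4), 0.05 for hippocampal genes (percentile 48.4) and 0.56 for thalamic and cerebellar genes (percentile 95.9). Of inhibitory genes Calb2, which marks a class of interneurons, was called higher in replicate 2 (log2 ratio 0.95) and 2 genes were called adjusted over the list alone. No presynaptic, postsynaptic or hippocampal gene was called over all genes, against 6, 1 and 1 adjusted over the list alone. For microglia the median was 0.03 (percentile 58.0), for endothelial and mural cells 0.08 (percentile 71.7), for immediate early genes 0.01 (percentile 77.2), for cell cycle genes -0.14 (percentile 2.56), for mitochondrially encoded genes -0.17 (percentile 11.6), for the X-linked list -0.16 (percentile 17.1) and for RNA-binding proteins -0.16 (percentile 3.96). These 7 lists, the excitatory list and the thalamic and cerebellar list had 0 genes called, over all genes and adjusted over the list alone.

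Over all genes, 100 of 11339 genes with 10 or more reads differed between the libraries after Benjamini-Hochberg adjustment of the two-sided exact binomial test, 41 higher and 59 lower in replicate 2, and 975 had an unadjusted p under 0.05. The test compares these libraries, not conditions, and weighs counting error alone. Several of the largest differences with 50 or more reads lay at loci where transcript models of more than 1 gene overlap. Gm49450, which lies over Tuba1a on chromosome 15, had 322 reads in replicate 1 and 1 in replicate 2, and Klhl10 had 0 and 190. When overlapping same-strand models of the locus were counted together, the values were 5714 and 4171 for Gm49450, 281 and 188 for Klhl10, 125 and 93 for Topbp1 (14 and 97 reads by gene) and 690 and 381 for Wdr92 (77 and 10 by gene). Gm10774 (72 and 1 reads), Anapc15 (91 and 16), the potassium channel gene Kcna1 (43 and 9), Rpain (21 and 42) and 2310075C17Rik (12 and 79, or 26 and 79 by locus) completed the 10 largest with Ttr. After reassignment the log2 ratio of 2310075C17Rik was 1.56 instead of 3.18, and without Genomic reads that of Kcna1 was -1.30 instead of -1.69 and did not pass. On annotated transcripts Rpain, at 0.98 instead of 1.49, and Kcna1, at -1.24, did not pass. Counting annotated transcripts alone left 35 genes called and leaving out reads of the class Genomic gave 176; without the Genomic reads the log2 ratio of Topbp1 turned to -1.17. That of Anapc15 turned to 0.73 on annotated transcripts and to 0.34 after reassignment. Across genes the log2 RPM of the libraries correlated with Pearson's r = 0.946 and Spearman's rho = 0.949, where genes are not independent replicates. The biological coefficient of variation estimated by edgeR was 0.0881.

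**Figure D2:**
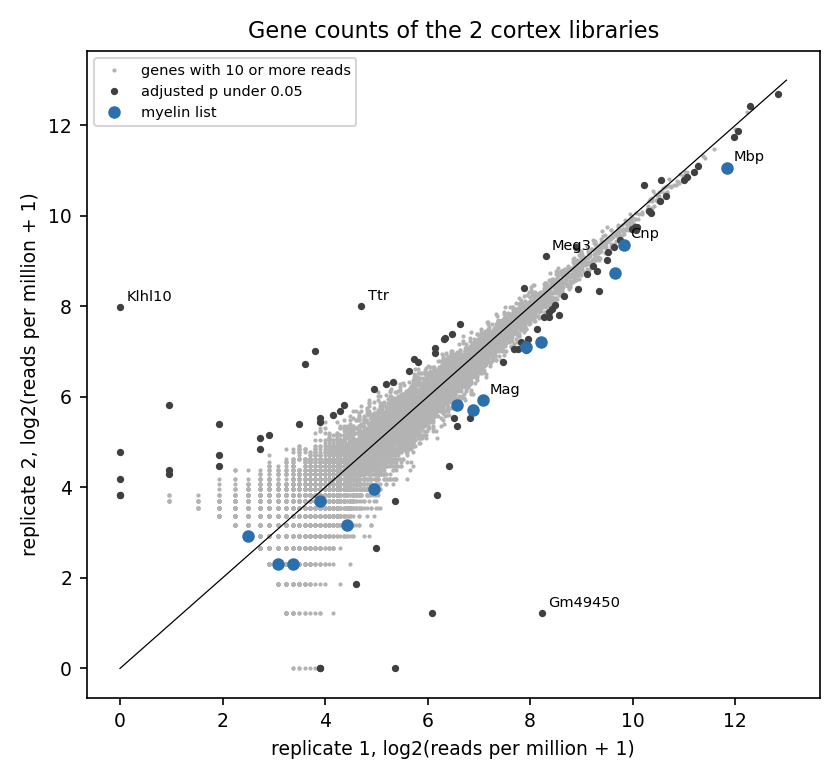
Log2(RPM + 1) of each gene with 10 or more reads in replicate 1 (x axis) and replicate 2 (y axis), with the line of equal values. Small points are all tested genes, dark points those with an adjusted p under 0.05 and blue points the myelin list, of which 13 of 14 genes had a negative log2 ratio of replicate 2 over replicate 1.

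Most reads came from annotated transcripts. Reads that matched an annotated transcript made up 65.5% ± 2.31, at 67.1% in replicate 1 (Wilson 95% interval 67.0 to 67.2) and 63.8% in replicate 2 (63.7 to 63.9). Incomplete splice matches took 9.82% and 10.4%, and 70.5% and 68.0% of these reads matched the 3' end of an annotated transcript. Models that the authors classed as annotated splice sites in a combination outside the annotation took 5.98% and 5.88%. Those classed as having a splice site outside the annotation took 3.89% and 3.69%. Reads antisense to annotated genes made up 6.69% and 9.15%, intergenic reads 0.736% and 0.879%, and reads of the class Genomic, which matched none of these, 5.80% and 6.15%.

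Splice chains outside the annotation were numerous but mostly rare. Of 33352 chains that the authors classed as annotated splice sites in another combination 16.4% were found in both libraries. Of 39812 chains classed as having a splice site outside the annotation it was 7.84%, against 64.0% of 22367 annotated chains. These 2 kinds follow the authors' labels and are not exact. The chains of Vdac3 and Hnrnpk, named after their values were seen, carried the first label in both libraries but held 1 splice site outside the annotation. A chain counted as found when it had 2 or more reads in 1 library and 1 or more in the other, which left 8603 unannotated chains. Recovery followed abundance: chains with a single read in replicate 1 were seen again in replicate 2 in 38.8%, 18.1% and 11.2% of annotated chains and of the 2 unannotated kinds, and chains with 10 or more reads in 99.9%, 99.8% and 99.7%. The most abundant unannotated chain belonged to Nrgn. It had 3070 and 2023 reads (2774 ± 126 RPM), 93.2% and 93.6% of the gene's reads, and an intron from 37545349 to 37545947 on chromosome 9 (mm10) outside the annotation. Oaz1 and Oaz2, which encode inhibitors of polyamine synthesis, also had most reads on a chain outside the annotation. These chains held 946 and 662 reads (95.9% and 95.5% of the gene) and 463 and 338 reads (92.0% and 89.7%). Unlike that of Nrgn, they held no new intron or splice site, and only the combination of annotated introns was outside the annotation. The cytoskeletal gene Sept7 had 633 and 336 reads on an unannotated chain with 1 intron outside the annotation between annotated splice sites. Apbb1, whose product binds the amyloid precursor protein, had 562 and 309 on an unannotated chain without a new intron.

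**Figure D3:**
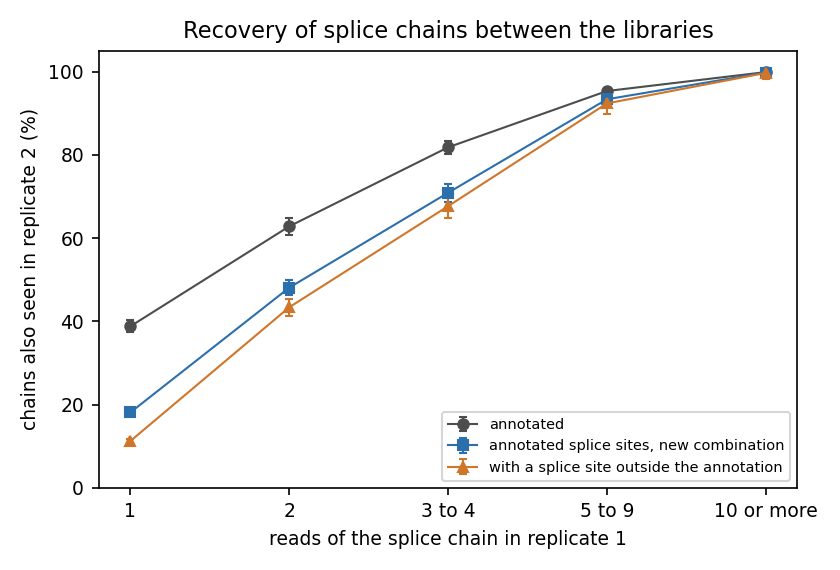
Percent of splice chains also seen in replicate 2 (y axis) by their number of reads in replicate 1 (x axis), for annotated chains, chains of annotated splice sites in another combination, and chains with a splice site outside the annotation. The 2 unannotated kinds follow the authors' labels. Bars are Wilson 95% intervals; recovery was 38.8%, 18.1% and 11.2% at 1 read and above 99% at 10 or more.

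Of 29484 unannotated loci, 674 had 10 or more reads in each library, and 635 of these lay antisense to an annotated gene. The most abundant lay opposite Gm26917, a ribosomal RNA locus on chromosome 17 (39843013 to 39848035, minus strand), with 3541 RPM in replicate 1 and 7939 in replicate 2. A locus opposite the 3' part of the glutamate transporter gene Slc1a2 on chromosome 2 (102777584 to 102789422) reached 3665 and 4053 RPM, against 338 and 369 RPM for Slc1a2 itself. Another locus opposite Snhg11 on chromosome 2 (158382138 to 158384699) had 1473 and 3018 RPM, against 79.3 and 154 on the sense strand.

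In most genes 1 isoform made up the bulk of the full-splice reads. Over 4968 genes with 20 or more such reads in each library, the dominant isoform held a median of 84.5%; it held over 50% in 4286 genes (86.3%) and over 90% in 1863 (37.5%). It was the same isoform in both libraries in 4728 genes (95.2%) and lay outside the annotation in 5.76%. Several synaptic and myelin genes split their reads. Ndrg4-202 held 43.7% and 38.8% of Ndrg4 reads and Ndrg4-203 held 33.7% and 37.1%. Snap25, a core protein of vesicle fusion, divided into Snap25-201 (74.2% and 70.7%) and Snap25-202 (23.7% and 26.9%). Cnp-201 held 55.3% and 59.5% against 43.1% and 37.6% for Cnp-204, and Syn1-202 held 55.8% and 55.4% against 42.2% and 40.2% for Syn1-201. Syn2-205 held 65.3% and 59.6% against 31.6% and 36.2% for Syn2-201. All introns of Cnp-204 also lie in Cnp-201, and those of Syn2-205 in Syn2-201. An incomplete read of the longer chain could therefore count for the shorter, and how many did was not tested. The small GTPase gene Cdc42 was near an even split, with Cdc42-201 at 54.0% and 46.8% and Cdc42-202 at 42.0% and 49.1%. Clstn1-202 held 46.9% and 54.4% and Clstn1-201 45.2% and 35.4%. In Rab3a and Rbfox3 the second isoform was unannotated, at 24.3% and 26.0% of Rab3a and 22.1% and 25.8% of Rbfox3.

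Isoform use differed between the libraries in 31 of 2828 genes by a chi-square test with 10000 simulated tables, and 228 genes had an unadjusted p under 0.05. In 18 of the 31 genes the deposited tables label 1 and the same splice chain as incomplete in 1 library and as a full unannotated transcript in the other. The 5 leading genes, Nrgn, Uchl1, Aplp2, Cpne6 and Camta2 (chi-square test with simulated tables, p = 0.0001, the smallest the simulation can give, adjusted p = 0.0135), were all of this kind: the Uchl1 chain had 388 and 266 reads in replicate 1 and 2, and the Cpne6 chain 191 and 149. With 1 label per chain in both libraries, 6 of 2847 genes differed, and these 6 were among the 31. All 6 stood at the smallest p of the simulation (adjusted p = 0.0475), so their number depends on that floor, and genes without such a label difference, among them Khdrbs3, Tspan31 and Kcnn2, were also lost. In Ddx5, an RNA helicase gene, Ddx5-201 held 79.7% of reads in replicate 1 and 66.6% in replicate 2; in Rpl38, Rpl38-201 held 50.5% and 26.8%; and in Ensa, Ensa-202 held 70.6% and 55.5%. The other 3 were Srsf5, Plppr2 and Gprasp2, and in the last pair the chain that differed had reads in both libraries under another gene or label (65 and 48; 16 and 8). These 6 genes were named after their values were seen.

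Single exons could be counted in reads that span them. Of 456 annotated alternative exons in 80 neuronal and glial splice genes, 90 in 44 genes had 20 or more spanning reads in each library and a mean inclusion of 5 to 95%. The choice in Snap25 lies between a pair of exons on chromosome 2: the exon from 136770057 to 136770174 was included in 75.8% and 72.1% of reads and that from 136769743 to 136769860 in 24.4% and 27.7%. In Pkm, the glycolytic enzyme pyruvate kinase, the exon at 59675029 on chromosome 9 stood at 87.1% and 82.7% and the exclusive partner at 59675568 at 12.8% and 17.02%. A pair of 115-base exons of the glutamate receptor gene Gria2 on chromosome 3 stood at 54.9% and 62.6% (80690404) and at 45.8% and 37.7% (80691320). In Mbp the 78-base exon at 82561778 on chromosome 18 was included in 23.2% and 23.9% of reads and the 123-base exon at 82578936 in 24.01% and 27.8%. In Grin1 the 63-base exon at 25311343 on chromosome 2 stood at 23.7% and 23.2% and the 111-base exon at 25294438 at 59.1% and 52.7%. The 168-base exon of App at 85043576 on chromosome 16 was included in 5.72% and 7.48%, whereas that of its relative Aplp2 at 31167561 on chromosome 9 was included in 87.1% and 87.3%; the mean of the latter was 72.4% without incomplete splice matches and 57.4% on annotated transcripts alone.

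None of the 90 exons differed between the libraries after adjustment of Fisher's exact test, and 8 had an unadjusted p under 0.05. The median absolute difference was 3.31 percentage points, with a largest of 25.5. Without incomplete splice matches 5 exons passed: both of the Pkm pair (Fisher's exact test, adjusted p = 0.0225 and 0.0226), and 3 of Aplp2 and Dctn1, genes with a chain labelled incomplete in replicate 2 alone. Where spanning reads were few the intervals were wide, as for the 30-base exon of Nrcam at 44566840, included in 65.5% of reads in replicate 1 (Wilson 95% interval 47.3 to 80.1) and in 10 of 25 in replicate 2 (23.4 to 59.3%).

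**Figure D4:**
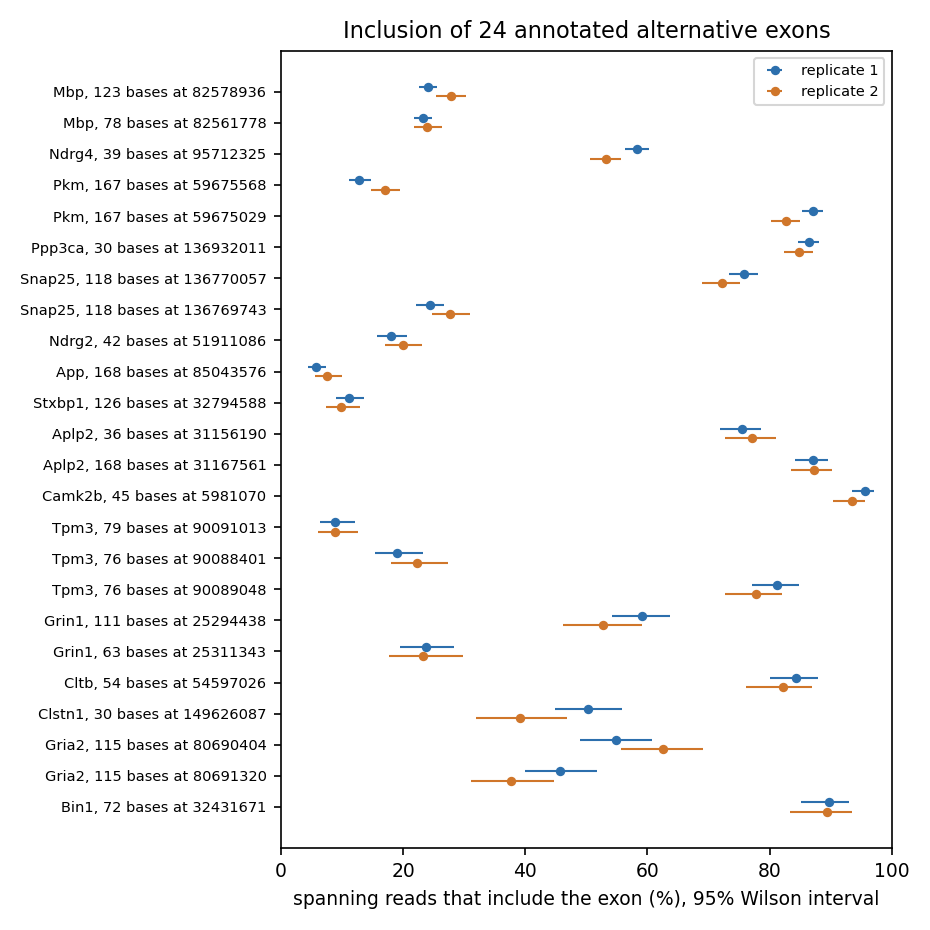
Percent of spanning reads that include each of the 24 alternative exons with the most spanning reads, in replicate 1 and replicate 2, with Wilson 95% intervals; labels give the gene, the exon's length and its start on mm10. The Snap25 pair lies at 75.8% and 72.1% and at 24.4% and 27.7%.

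The reads reached transcripts of several kilobases. Weighted by reads, annotated multi-exon transcripts had a median annotated length of 2229 bases in replicate 1 and 2220 in replicate 2, a 90th percentile of 4221 and 4195 bases and a median of 7 exons, and 2.77% and 2.69% of reads came from transcripts over 6 kilobases. The longest with 5 or more reads in each library, by annotated length, were D10Wsu102e-201 (123179 bases), D1Ertd622e-201 (40378), Hnrnpr-207 (21452), Serbp1-201 (15474) and the potassium channel subunit transcript Dpp10-202 (15297, with 15 and 16 reads). A read assigned to a model need not cover its whole annotated length.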

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

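Of the tests below, those of transcript length and of priming at A-rich stretches were chosen before their result was seen; the tests of locus counts, the precursor list, the striatal list and spike-in strand were chosen after. The design holds 1 group and gives no biological comparison for these patterns; of biological explanations only the cell and tissue composition of the libraries is weighed here.

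Antisense reads, which enter no gene comparison, made up 6.69% of mouse reads in replicate 1 and 9.15% in replicate 2, and 6.35% and 8.42% without the ribosomal RNA locus on chromosome 17. That locus alone had 3797 and 5982 reads on the strand opposite its annotation. Antisense reads also appeared on spike-in RNAs, which have no antisense transcript: 87 and 56 on ERCC-00009 and 40 and 20 on ERCC-00116, all above the 3 counts that a count of 0 allows. Neither had a sense read.

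For the single-exon antisense reads, a general turning of reads to the wrong strand is argued against by the spike-ins, whose antisense share was 0.614% (143 of 23305 reads on 16 RNAs). All 143 were on ERCC-00009, and the other 15 RNAs had 0 antisense reads, so the share describes 1 RNA read on that strand alone and not a part of the reads of each. Priming at A-rich stretches of the antisense strand may account for a part of them. The search read sequence alone and does not show whether the primed strand was an RNA. The models searched held 33892 reads, 24.6% of all single-exon antisense reads, and 31.4% of these ended next to 10 or more A in 20 bases, 2.97 times the share at random positions of the same exons (10.6%); over models instead of reads it was 5.10 times (53.1% against 10.4%). The rest of these reads was not searched, and true antisense transcripts stay open.

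The lower myelin genes of replicate 2 do not follow transcript length, since random lists matched on expression and length had a lower 95% limit of -0.22 against the list's median of -0.86. Fewer cells of the whole oligodendrocyte lineage are argued against by the precursor list. Its median log2 ratio was -0.014, above -0.43, the bound set at 50% of the myelin median. The bootstrap 95% interval, -0.25 to 0.32, resampled the list's 12 genes and carries no error between libraries. Of these genes 6 were higher in replicate 2. More tissue from under the cortex in replicate 1, such as white matter with striatum, may account for the lower myelin genes: the striatal list also lay low, at percentile 0.22. Its members were not uniform: of 10 genes 3 were higher in replicate 2, 8 had enough reads to be tested and 1 was called over all genes. The explanation does not extend to all tissue outside the cortex. The choroid plexus and meninges list was higher in replicate 2, with a median of 0.92 (percentile 99.8). The thalamic and cerebellar list, at 0.56, stayed within the middle 95% of matched lists. A difference between the animals stays open.

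Of 25 genes with a 4-fold or larger difference between the libraries, 11 (44%, Wilson 95% interval 26.7 to 62.9) differed less than 4-fold by a locus count, among them Gm49450, Klhl10, Topbp1 and Wdr92. That count takes same-strand models that overlap the gene's most-read model by 50% or more both ways, so it cannot join models that overlap less. The interval includes 50% and treats the genes as independent, which genes at 1 locus are not. The assignment of 1 locus to different genes therefore cannot be told apart from other causes for most of these genes. By the locus count 14 genes stay open. Ttr keeps its difference by locus, with 25 and 188 reads (log2 ratio 3.40), while for Gm10774, which lies inside Usp50 on chromosome 2, and for Usp50 the directions are opposite, with 72 and 1 against 1 and 42 reads, as the assignment of 1 locus to different genes would give although the locus count did not join their models; Usp50 was chosen after its values were seen.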

How the results depend on the processing

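Of the alternatives below, the reassignment of models by exon overlap, 1 label per chain and leaving out the ribosomal RNA locus were chosen after seeing the data. No paired analysis was possible because the series has 1 group. The count of genes that differ between the libraries was 100, against 95 with TMM, 94 with median-of-ratios, 85 without a filter, 93 at 50 or more reads, 100 without mitochondrial genes in the total and 86 after reassignment (78 shared). It rose to 176 (80 shared) without Genomic reads and fell to 35 (28 shared) on annotated transcripts alone. Of 96 genes called only without Genomic reads, 47 had Genomic reads in 1 library alone, such as Ywhag with 0 of 303 and 203 of 234 reads. For these the setting removed reads from 1 library alone, and whether like reads were labelled differently was not tested. For the others and for annotated transcripts the cause was not tested. Reversed log2 ratios were Topbp1 -1.17, Nnat -0.081 and Snhg11 -0.75 without Genomic reads, Anapc15 0.73 and Topbp1 -0.86 on annotated transcripts, and Anapc15 0.34 and Klhl10 -0.062 after reassignment, where reads moved between overlapping genes by construction. Mbp, Cnp, Trf and Ttr passed under every alternative that tested them. Besides the reversed genes, Kcna1, Calb2 and Dpysl3 did not pass without a filter, nor Kcna1 without Genomic reads (-1.30), nor Tuba1a (0.055) and Dpysl3 after reassignment, nor 9 genes followed by name on annotated transcripts. Without Genomic reads the excitatory, inhibitory and postsynaptic lists lay low, at percentiles 0.49, 2.40 and 0.94. How far reads labelled Genomic in 1 library alone set these shifts was not tested. The biological coefficient of variation was 0.0838 at 50 or more reads against 0.0881.

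The annotated share of reads was 70.9% on models with 2 or more reads, which drops single-read models by construction, and 63.8 to 67.1% with 1 library left out. Unannotated chains found in both numbered 1521 at 5 or more reads in each and 12462 at 1 or more, against 8603. The dominant isoform's median share was 74.8% with incomplete matches counted, 98.2% on annotated transcripts, 88.3% at 50 or more reads, and 83.7 to 84.4% with 1 library left out; the cause of the change at 50 reads was not tested. Isoform use differed in 31 genes, in 4 on annotated transcripts, in 27 at 50 or more reads and in 6 with 1 label per chain. Reported exons numbered 47 on annotated transcripts and 91 to 109 with 1 library left out, against 90. Median length was 2275 bases over all spliced classes and 2220 to 2229 with 1 library left out. Lists outside the middle 95% of matched lists numbered 7, and 7 to 9 under the alternatives; lists with a high level numbered 8, and 6 to 8 with 1 library left out. Chains with 1 read in replicate 1 were mostly not seen again, at 38.8% recovered for annotated chains and 18.1% and 11.2% for the 2 unannotated kinds. At 5 to 9 reads in replicate 1 recovery was 95.3%, 93.3% and 92.4%. A single read does not fix how abundant a chain is, so whether depth alone sets recovery was not tested. Genes under 10 reads were not tested.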

Other observations

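The hypothesis below was formed after the differences between the libraries were seen; the test of nuclear RNAs was chosen before the values of its 3 genes were seen.

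Some called genes outside the lists fixed beforehand are given here as values; these names were chosen after their values were seen, so they show no theme. Nefm, a neurofilament gene, had 267 and 117 reads in replicate 1 and 2 (log2 ratio -0.68) and Nefl 1403 and 806 (-0.29). Gsn, an actin-severing protein abundant in oligodendrocytes, had 698 and 245 reads (log2 ratio -0.999). Ptgds, an enzyme of meninges and oligodendrocytes, had 1286 and 1246 reads (log2 ratio 0.46), and the hypothalamic hormone gene Avp had 0 and 13 reads.

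Meg3 and Snhg11, RNAs kept mainly in the nucleus, were higher in replicate 2, so replicate 2 may hold more nuclear RNA. The annotation used types Meg3 as non-coding and Snhg11 as protein-coding. The summed reads of Malat1, Miat and Neat1, nuclear RNAs with 62 and 53, 80 and 83, and 2 and 1 reads, had a log2 ratio of 0.44. Its exact interval from counting error alone was 0.09 to 0.78, but with the spread between the libraries (coefficient of variation 0.0881) added it was -0.06 to 0.93, so the explanation cannot be told apart from no difference at this depth. The wider interval was adopted after the narrower one had been seen. Xist, Rian, Mirg and Kcnq1ot1 were left out because their values were already known; with them the log2 ratio of the 7 RNAs was also 0.44. Without Genomic reads Snhg11 turned to -0.75 while Meg3 stood at 0.93, and on annotated transcripts Meg3 fell short of the threshold (0.13).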
